A study of Drosophila melanogaster with 4 samples.

How the data were processed

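Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K9me1, histone H3 monomethylated at lysine 9, in whole Drosophila melanogaster embryos of the wild-type Oregon-R strain aged 14 to 16 h. The study has 4 samples: 2 ChIP samples made with a new lot of the antibody and 2 input samples of chromatin that was not precipitated, numbered 1 and 2 in each group. Embryos were fixed in 1.8% formaldehyde and the chromatin was incubated with the antibody for 15 h, per the labels' protocols. Nothing in the labels says whether the replicates came from separate embryo collections, so the spread between them may be technical.

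Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The files used here are 3 lists of regions of significant enrichment ("clusters"): 1 per ChIP replicate and 1 combined list for the replicate set. Coordinates are on FlyBase release 5, per the file headers, and are given here counted from 1. The labels state that each input sample served as the control of the ChIP list with the same number. The caller, its threshold and how the combined list was made are not given in the sources used here. No values of the input samples were analysed here, so no value below has a separately measured background; the clusters are regions that the authors called, with the input as their stated control. Read counts and depths were not used here, so the depth of each library is unknown and no counting interval or detection floor is given.

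Each cluster carries a score in the deposited lists, and its scale is not stated. The scale was therefore tested on the values. When 2 was raised to the score and divided by 1 constant per list (0.982, 0.978 and 0.980 for replicate 1, replicate 2 and the combined list), the result was a ratio of whole numbers, with a denominator of at most 500 and a relative tolerance of 1e-11, for 99.8%, 98.9% and 91.2% of the clusters. After each value was rescaled at random by up to 1%, 0% were. The score is accordingly read here as a log2 ratio, and enrichment folds below are 2 raised to the score. The whole numbers were not used as read counts.

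The covered bases of each list were taken on the 13 sequences that hold clusters: the 5 long arms (X, 2L, 2R, 3L and 3R), the fourth chromosome (4), the 6 sets of heterochromatic scaffolds (names ending in Het) and the unplaced scaffolds (U), 139.7 Mb together. Uextra, 29.0 Mb of further unplaced scaffolds, is named in the headers and holds 0 clusters in all 3 lists; it was left out of the genome length. Clusters that ran past the end of a sequence, at most 2 per list and by at most 804 bp, were cut at the end. Assembly gaps and repeats that reads cannot be assigned to count as uncovered; their lengths were not measured here.

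Overlap of the replicates was tested one-sided by circular shifts: the clusters of one list were rotated by a random amount within each sequence, which keeps their number, width and spacing, with 100000 draws for the replicates and 10000 for the combined list. Coverage of each sequence was tested two-sided on the bases covered in both replicates, by rotating them around the joined genome over all 1397124 shifts of 100 bp, with Benjamini-Hochberg adjustment over the 13 sequences. A sequence was called only with an adjusted p under 0.05 and both replicates on the same side of the genome average. Neighbouring shifts compare nearly the same bases, so for a long arm few of the 1397124 shifts are separate placements. A p-value of this test is therefore a coarse guide, and a sequence that did not pass is not shown to lie at the genome average. These tests compare positions in these lists; no test across samples was used, because with 2 ChIP samples an exact sign-flip permutation test of a contrast within samples cannot go below p = 0.5 (two-sided). Coverage was also described in windows of 1 Mb (a last window under 500000 bp was left out). Scores were compared across clusters that overlapped one to one.

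Tests were checked on simulated lists of 5480 clusters. Among 100 pairs of random lists, 4 passed the overlap test, and among 100 random lists 4 had any sequence called. With X raised 2-fold, X was called in 20 of 20 lists, at a mean recovered fold of 1.94. Simulated clusters were placed independently at random within each sequence, so the check does not cover lists that clump along an arm. Sequences were called there on a single list, without the rule on both replicates. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

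The regions named were chosen by a rule fixed before the data were examined: the 10 highest-scoring and the 5 longest clusters of the combined list of which each replicate covers at least 50%. The alternatives fixed at the same time were clusters at or above the median score, clusters of at least the median width, stricter overlap, each replicate alone, the combined list, clusters per Mb in place of bases, and other reference sequences. Tests of gene features and gene lists had also been planned. They were not run, because the gene table at hand is on release 6 and no coordinates were converted; no gene is assigned to a region here.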

Results

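H3K9me1 clusters were mapped in 2 ChIP replicates of 14 to 16 h Oregon-R embryos, each called with its own input. H3K9me1 covered a similar share of the genome in the 2 replicates. Replicate 1 held 5480 clusters over 12.02 Mb (8.61% of the 139.7 Mb examined) and replicate 2 held 6062 clusters over 14.6 Mb (10.4%), a mean of 9.51% ± 1.28 (SD, n = 2). The clusters were narrow, with a median width of 1907 bp ± 66 (SD, n = 2) and none under 1301 bp in either replicate. Enrichment was modest. The median deposited score was 0.72 ± 0.03 (SD, n = 2), a 1.65-fold ± 0.03 ratio on the scale described above, and 5% of clusters lay above 2.01-fold in replicate 1 and 2.00-fold in replicate 2.

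The first comparison asked how far the replicates mark the same regions. Bases covered in both replicates came to 7.41 Mb, 5.30% of the genome, which is 61.6% of the bases of replicate 1 and 50.9% of those of replicate 2. Of the clusters, 66.5% of replicate 1 and 57.6% of replicate 2 touched a cluster of the other replicate by at least 1 bp (mean 62.0% ± 6.3, SD, n = 2). The Jaccard index, shared over total covered bases, was 0.386 against a mean of 0.0558 for rotated lists. The overlap was 5.28-fold that of rotation (circular-shift permutation test, one-sided, p = 1e-05, the smallest that 100000 draws can give). Agreement was similar on the 5 long arms, with Jaccard indices from 0.371 on 3R to 0.416 on X, and lowest on YHet at 0.178. The 2766 one-to-one pairs held 50.5% of the clusters of replicate 1 and 45.6% of those of replicate 2. Across these pairs scores rose together: Spearman's rho was 0.53 and Pearson's r 0.60 (permutation p = 1e-05 for each of the 2 coefficients, the smallest possible). Clusters are not independent replicates, and those without a single partner are left out of these coefficients. Without the 2 clusters farthest from the median score r was 0.58.

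The second comparison asked on which chromosomes the mark lies. The X chromosome had a larger share of its bases inside clusters than any other long arm in both replicates. Clusters covered 16.3% ± 2.4 of X (SD, n = 2; 14.6% and 18.0%) against 8.41% ± 0.80 of the combined length of the 4 autosomal long arms (7.84% and 8.98%), a ratio of 1.94 ± 0.10. X makes up 16.1% of the length examined and held 27.5% ± 0.3 of the covered bases. The clusters on X also had higher scores, with medians of 0.83 in replicate 1 and 0.78 in replicate 2, against 0.70 to 0.71 and 0.67 on the autosomal long arms. X was the 1 sequence of 13 that passed the test: bases covered in both replicates were 1.81-fold the genome average (circular-shift permutation test, two-sided, adjusted p = 0.0273). Because X makes up 16.1% of the length, few of the placements compared are separate, and this p-value is a coarse guide. Input values for X were not analysed here, and the labels give no sex for the embryos.

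**Figure D1:**
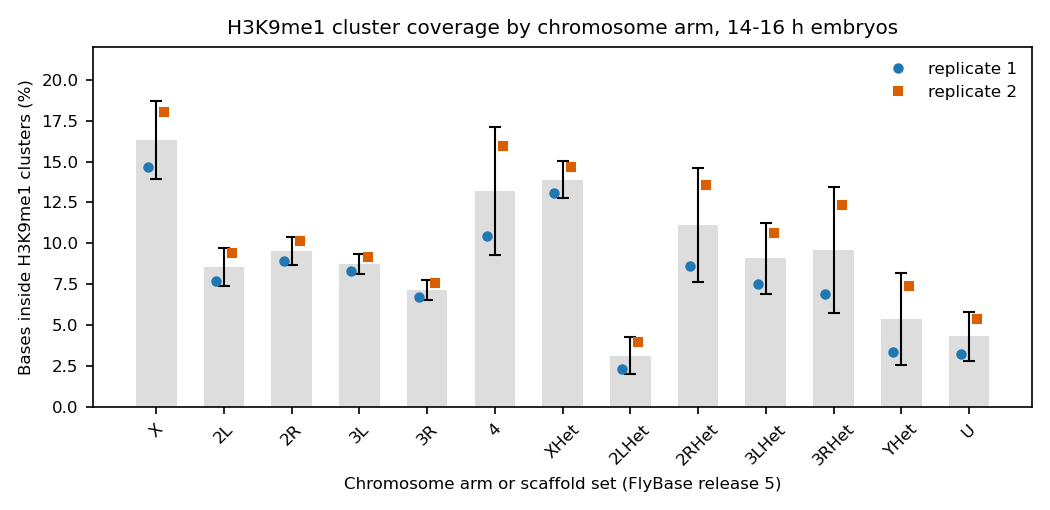
Percent of each chromosome arm or scaffold set inside H3K9me1 clusters (vertical axis) for the 13 sequences that hold clusters (horizontal axis); circles are replicate 1, squares replicate 2, grey bars their mean and error bars the SD (n = 2). X lies at 14.6% and 18.0%, above the 4 autosomal long arms, which lie between 6.72% and 10.1%.

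The autosomal long arms lay near or below the genome average and did not pass the test. Coverage was 9.54% ± 0.84 of 2R, 8.73% ± 0.62 of 3L, 8.55% ± 1.18 of 2L and 7.16% ± 0.62 of 3R (SD, n = 2). On 3R this was 0.75-fold ± 0.04 the genome average in single replicates (adjusted p = 0.853, circular-shift permutation test on bases covered in both).

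The fourth chromosome, a small and largely heterochromatic autosome, was covered at 10.4% in replicate 1 and 16.0% in replicate 2 (13.2% ± 3.9, SD, n = 2), and XHet, the heterochromatic scaffolds of X, at 13.9% ± 1.1. Their folds over the genome average in bases covered in both replicates were 1.33 and 1.49, and neither passed the test (adjusted p = 0.977 for each, permutation of positions). The value of the fourth chromosome fell to 0.271-fold when clusters under the median score of their list were left out. Its own median scores were the lowest of the 13 sequences (0.67 and 0.64). Among the other heterochromatic scaffolds, coverage was 11.1% ± 3.5 of 2RHet, 9.61% ± 3.86 of 3RHet, 9.08% ± 2.18 of 3LHet and 3.14% ± 1.13 of 2LHet. YHet was covered at 5.37% ± 2.83 and the unplaced scaffolds U at 4.31% ± 1.48. None of these passed the test, and YHet rests on 6 and 12 clusters in replicates 1 and 2. The values of 2LHet rest on 5 and 5 clusters and those of XHet on 12 and 11.

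Coverage also varied along the long arms. Of the 22 windows of 1 Mb on X, 21 exceeded the autosomal median in each replicate. The median X window was covered at 14.6% in replicate 1 and 17.5% in replicate 2, against 7.14% and 7.43% for 97 autosomal windows. The most covered window was X from 19000001 to 20000000 (23.9% ± 4.9, SD, n = 2), followed by X from 6000001 to 7000000 (22.5% ± 1.2). The third was the centromere-proximal window of 2L, from 22000001 to 23000000 (21.8% ± 3.2). The least covered was 3R from 22000001 to 23000000 (2.38% ± 0.12). On the autosomal arms the 2 Mb next to the centromere were covered at 19.6% ± 3.4 on 2L, 16.1% ± 2.6 on 2R, 15.2% ± 1.8 on 3R and 14.9% ± 2.9 on 3L. The rest of these arms was covered at 7.49% ± 0.98, 8.85% ± 0.65, 6.54% ± 0.53 and 8.18% ± 0.42 respectively. On X the proximal 2 Mb were at 16.1% ± 6.0 and the rest at 16.3% ± 2.0.

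**Figure D2:**
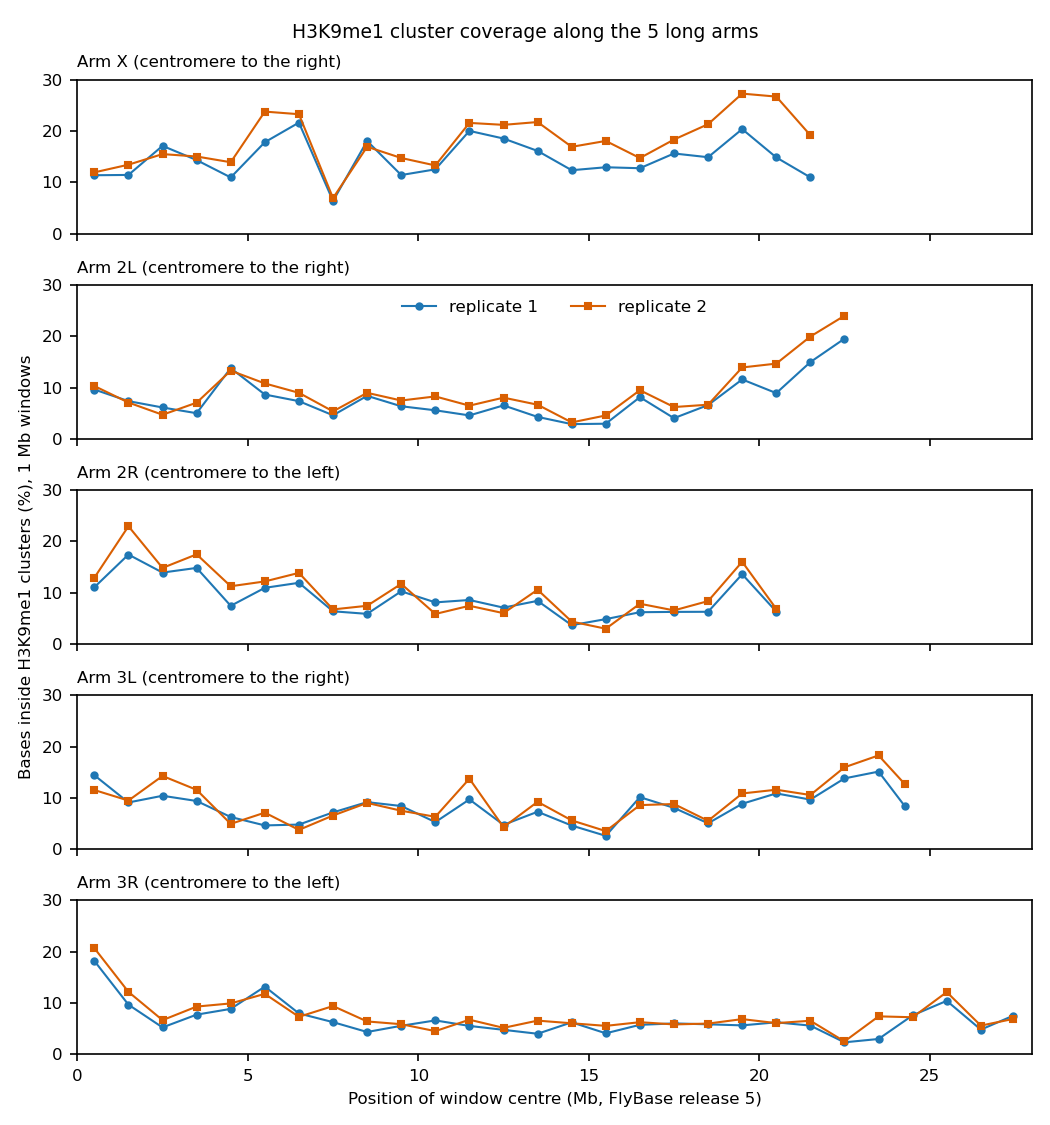
Percent of bases inside H3K9me1 clusters (vertical axis) in 1 Mb windows along the 5 long arms (horizontal axis, position in Mb), with circles for replicate 1 and squares for replicate 2. On 2L coverage is highest at the centromeric end, at 19.5% and 24.0% in the last window drawn, while X is above the autosomal median in 21 of 22 windows.

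The third comparison set the combined list against the replicates. It was made from the same samples and is no independent evidence. The combined list held 13114 clusters over 32.6 Mb, 23.3% of the genome and 2.45-fold the mean of the replicates. It contained 97.7% of the bases of replicate 1 and 98.4% of those of replicate 2 (3.79-fold and 3.81-fold the overlap of rotated lists, circular-shift permutation test, one-sided, p = 0.0001 for each, the smallest that 10000 draws can give). Of its own bases, 22.7% lay in both replicates and 42.8% in neither. The 6190 combined clusters that no replicate touched had a median score of 0.48 and a median width of 1344 bp. The 3118 touched by both replicates had a median score of 0.62 and a median width of 3907 bp. Among the 5 long arms X led here too, at 37.3% of its bases against 21.1% of the autosomal long arms. XHet lay at 38.7%, with only 30 combined clusters. X held 62 of the 163 combined clusters of 10 kb or more, or 2.77 per Mb, and 3RHet held 8, or 3.18 per Mb. The density on X was close to that on 2RHet (9 clusters, 2.74 per Mb) and above that on the fourth chromosome (3 clusters, 2.22 per Mb).

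Of the combined clusters, 2115 were covered over at least 50% of their length by each replicate, and 528 of these lay on X. That was 17.9% of the combined clusters on X, against 16.1% of all combined clusters. The 5 longest of the 2115 were 4 clusters on X and 1 on 2R. The longest ran from 16353456 to 16386254 on X (32799 bp) with a score of 0.80, and 71.2% ± 20.4 of it was covered in single replicates (SD, n = 2). The next were X from 17867086 to 17892613 (score 0.82, 80.7% ± 7.5 covered), X from 12194892 to 12218464 (score 0.86, 67.9% ± 8.9) and 2R from 3216105 to 3239486 (score 0.79, 75.2% ± 23.1). The last was X from 19697836 to 19720905 (score 0.80, 69.6% ± 10.7), inside the most covered window.

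**Figure D3:**
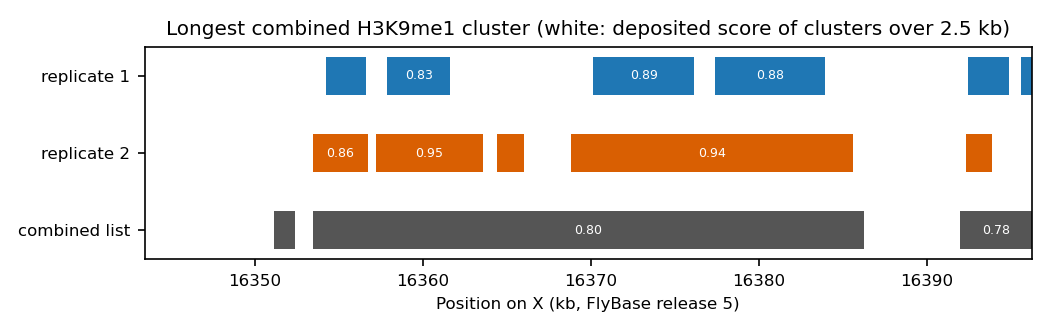
Clusters of the 2 replicates and the combined list (vertical axis) over the longest combined cluster, from 16353456 to 16386254 on X (horizontal axis, position in kb), with the deposited score in white. Each replicate shows 4 separate clusters where the combined list has 1.

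Of the 10 highest-scoring clusters of this class, 8 lay on the unplaced scaffolds U, which carry sequence not assigned to a chromosome. The highest ran from 3774396 to 3777317 on U with a score of 2.28, a 4.84-fold ratio, and the highest scores of the replicates within it were 2.51 and 2.13. The second, from 8484316 to 8486610 on U, scored 1.498, and the third, from 5098244 to 5102060 on U, scored 1.41. The others on U started at 2137782 (score 1.32), 7523609 (1.27), 5082591 (1.22), 2774109 (1.21) and 5277742 (1.17). The 2 on long arms were 2L from 5012438 to 5019557 (7120 bp, score 1.22, 92.0% ± 5.6 covered) and 3L from 11953093 to 11958311 (5219 bp, score 1.16, 92.3% ± 4.5 covered; SD, n = 2). Scores of the highest rank were seldom shared: of the 50 highest-scoring clusters of the whole combined list, 27 lay on U and 2.0% touched a cluster of either replicate, against 53.0% of the rest. Their median width was 1014 bp, and 42 of them were narrower than the 1301 bp minimum of the replicates.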

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

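The Jaccard index of the replicates stayed between 0.322 (clusters at or above the median score) and 0.390 (without heterochromatin and unplaced scaffolds), and passed the test in each of 3 alternatives. The share of clusters that touch the other replicate, 62.0%, moved to 54.5% when 50% of the cluster had to be covered and to 45.7% with reciprocal overlap of 50%. X kept its direction and its call in all 7 alternatives, with folds from 1.60 (combined list) to 2.63 (clusters at or above the median score) and adjusted p from 0.00195 to 0.0429. The latter was replicate 1 alone. The largest fold and the smallest p came from the cut at the median score. That cut favours X, whose clusters scored higher, so it is no independent support. Leaving out 1 replicate gave 1.70 and 1.73. The number of sequences called was 1 throughout. The other 12 sequences were not called under any alternative, but several had folds on both sides of 1: 2R, the fourth chromosome, 2RHet, 3LHet and 3RHet, and 2L and 3L when Uextra was counted in the genome length. The difference of 1 Mb windows between X and autosomes was 4.99 percentage points in bases covered in both replicates, 6.83 and 9.02 in single replicates and 16.2 in the combined list. Combined clusters at or above the median score still contained 79.3% and 80.5% of the bases of replicates 1 and 2. Spearman's rho of the scores was 0.58 with reciprocal overlap and 0.52 on the 5 long arms. The settings with Uextra and those for windows, for the centromere-proximal 2 Mb and for the number of combined clusters covered by each replicate were chosen after seeing the data. No paired analysis was possible because the input samples, which share their numbers with the ChIP samples, have no values here. Planned tests of gene features and gene lists were not run, for lack of coordinates on the same release. Library depth is unknown, so a region outside the clusters is not shown to lack the mark.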

Other observations

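The tests below were chosen after the results were seen, except the test of replicate agreement (kappa) near the centromeres and the share of narrow clusters in the combined list, which was chosen when the minimum widths were known and the share was not. On the 4 autosomal long arms, H3K9me1 coverage was higher in the 2 Mb next to the centromere than in the rest of the arm in both replicates. The ratio was 2.61 ± 0.11 on 2L, 2.32 ± 0.08 on 3R, 1.81 ± 0.16 on 2R and 1.81 ± 0.26 on 3L (SD, n = 2). In bases covered in both replicates the mean difference was 5.59 percentage points (circular-shift permutation test within arms, one-sided, p = 4e-05). It was 10.1 points without replicate 1, 7.26 without replicate 2 and 15.7 in the combined list, which cover more bases than those shared by both replicates. Taken singly, 2L, 3L and 3R passed (adjusted p = 0.0447 for each) and 2R did not (adjusted p = 0.0953), by permutation of positions. On X the ratio was 0.80 in replicate 1 and 1.15 in replicate 2 (adjusted p = 0.706, the same permutation of positions). The 2 Mb were picked after the windows had been seen, so these p-values describe the difference and are no independent test of it. Coverage did not go on rising into the heterochromatic scaffolds of these arms, which lay at 3.14% on 2LHet, 11.1% on 2RHet, 9.08% on 3LHet and 9.61% on 3RHet. The gap and repeat content of these scaffolds was not measured. Noise in single libraries was first tested by kappa, the chance-corrected agreement of the replicates. It was 0.514 in the proximal 2 Mb and 0.502 in the rest, a difference of 0.012 ± 0.026 (SD, 4 arms). Noise predicted a lower kappa near the centromere on every arm, and it was lower on 3L only. The outcome written for no noise, a mean at or above the rest, was met by less than the spread. The prediction for noise was thus not met, but kappa alone was taken to leave the question undecided. In a second test, chosen after that result, independent noise would have added 2.09 points to the bases covered in both, 3.49 fewer than observed. This test used the same single coverages and shared bases as kappa and is no separate evidence. A bias shared by both libraries, such as reads from repeats, was not tested.

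The excess on X was the only call by chromosome. Noise in single libraries was first tested by kappa, which was 0.509 on X and at lowest 0.498 on the autosomal long arms, a gap within their SD of 0.014. A second test, chosen after that result, used the same single coverages and shared bases as kappa. It is therefore no separate evidence. X exceeded the single autosomal arms by a mean of 4.93 percentage points in bases covered in both replicates. The product of the single coverages gave 1.91, and the gap held against each of 4 arms. These values argue against an excess on X made of independent noise alone. Explanations that stay open include one offset of the ChIP over input ratio for the whole of X. Scores on X were higher by 0.12 ± 0.01 at the median, 0.10 ± 0.02 at the 5th percentile and 0.14 ± 0.01 at the 95th (SD, n = 2). An offset was expected to raise scores on X, and so was a mark that is truly denser there. A higher score floor for calls on X would also raise them. Without input values and the threshold of the caller these cannot be told apart. The labels give no sex, so no biological explanation was tested.

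The highest scores of each list were rarely shared. Of the 50 highest-scoring clusters, 36.0% of replicate 1 and 24.0% of replicate 2 touched the other replicate, against 66.8% and 57.8% of the rest. Location differed as well, since 56.0% and 74.0% of these clusters lay on U, against 2.27% and 2.81% of the rest. On U 32.1% and 24.3% of them touched the other replicate, against 78.0% and 52.7% of the other clusters there. On the remaining sequences 40.9% and 23.1% did, against 66.5% and 58.0%, in lists of 22 and 13 top clusters. In the combined list 2.0% touched either replicate, against 53.0% of the rest, but width differed too: 42 of these 50 were narrower than 1301 bp, the minimum of the replicates. None of the 42 was touched, against 7.98% of the other combined clusters as narrow, and 1 of the remaining 8 was, against 66.6%. The 50 combined clusters held 16 distinct scores, where random sets of 50 had a median of 50 and never under 46 (permutation p = 0.0001, the smallest possible). The 50 of replicates 1 and 2 held 46 and 44 against the same median (permutation p = 0.004 and 0.0003), and their median widths were 1600 bp and 1985 bp against 1014 bp in the combined list. Clusters taken by rank keep equal scores together, while random sets scatter over the list. These p-values therefore cannot show that scores repeat more at the top than elsewhere. The whole lists held 3001 distinct scores among 5480 clusters, 3759 among 6062 and 7838 among 13114 (replicate 1, replicate 2 and combined). Set against these whole lists, scores repeated more among the 50 combined clusters and less among the 50 of each replicate. A long list leaves more room for equal scores than 50 clusters do, so the lower repetition in the replicates decides nothing. Whether the highest scores were set by ratios of few reads stays open. Read counts were not at hand to test it directly.

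The combined list was 2.45-fold longer than the replicates. Combined clusters that no replicate touched scored lower than the rest, by a median difference of -0.064. Those touched by 1 replicate had a median score of 0.49 and those touched by both 0.62, against 0.48 for the untouched. A lower score of clusters that no replicate called is close to fixed by the way they were picked, so weaker enrichment reached in the combined data stays open. The list's shorter minimum width (1001 bp against 1301 bp) is argued against as the whole source. Clusters under the replicates' minimum were 45.8% of those untouched, and without them the combined list was still 2.19-fold longer. A different threshold of the caller may also play a part and was not tested.

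Replicate 2 covered more than replicate 1 on each of the 13 sequences. Its coverage was 1.11-fold to 1.23-fold that of replicate 1 on the 5 long arms and 1.12-fold on XHet. On the other 7 sequences it was 1.41-fold (3LHet) to 2.19-fold (YHet), and 2LHet and YHet rest on 5 and 6 clusters of replicate 1.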
